A study of Danio rerio with 9 samples.

How the data were processed

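RNA was measured by sequencing in 9 libraries from AB wild-type zebrafish (Danio rerio) embryos at the 128-cell, 256-cell and 512-cell stages. Per the labels' protocols, the uridine analogue 4-thio-UTP (50 mM, 1 nl) was injected into 1-cell embryos. It is built into new RNA, which was then biotinylated and purified on streptavidin beads. Libraries were made from amplified cDNA with 15 PCR cycles, per the labels' protocols. Labelled RNA has 2 libraries per stage, which the labels call technical replicates, so the p-values of the stage comparisons measure technical spread only. Unlabelled embryos, whose RNA went through the same purification, have 1 library per stage. The labels give the injection protocol for all 9 samples and call 3 of them unlabelled; these are taken as not labelled, and whether they were mock-injected is not stated.

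The deposited values are FPKM (fragments scaled by transcript length and library size). Per the submitters' processing notes they come from CASAVA 1.7, TopHat 1.3.3 and Cufflinks 2.0.2 on the genome build Zv9. The version of the gene annotation, filters on genes, the handling of reads with several matches and the scaling between libraries are not stated. A gene table gives FPKM per library, per the file headers. A further gene table and a transcript table hold 1 deposited FPKM value per stage over the labelled libraries, with a scaling between stages that is not stated. No read counts were used here, so the depth of each library is unknown, and no counting interval or detection limit is given. A search for common steps among low values, which would reveal the depth, found none.

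The per-library table has 8969 gene IDs, of which 7028 (78.4%) have a symbol and 1941 do not; symbols are printed in the case they carry. Sets of IDs with identical values in all 9 libraries hold 94 IDs, and reads shared between near-identical copies cannot be told apart in these values. Strand handling is not stated. An annotation of the build was not used here, so gene length, exon number and positions were not analysed here.

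Genes with at least 1 FPKM in at least 2 libraries of a fit were tested, which left 7438 genes in the fits of labelled libraries and 7697 in those with all 9. Values were taken as log2(FPKM + 1), with a pseudocount of 1. Tests used limma 3.58.1 in R 4.3.3 (linear fits, contrasts and moderated variances with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The stage comparisons used the 6 labelled libraries together, with 1 shared estimate of the spread. Labelled against unlabelled RNA over the 3 stages was tested on 3 labelled values, each the mean of 2 technical replicates, and 3 unlabelled values, with stage as a block. Labelled against unlabelled RNA at each stage, and the difference of the 512-cell against 128-cell change, were tested on group means of all 9 libraries. There, the single unlabelled library of a stage is assumed to vary like the labelled technical replicates. Calls test the deposited scale. Log2 changes of single genes and medians of lists are given relative to the median of all tested genes in that comparison, unless called fitted.

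Replicate numbers of the labelled libraries were checked for pairing by the correlation, across 7438 genes, of the replicates' deviations from their stage mean. It was 0.739 between 128-cell and 256-cell, 0.762 between 256-cell and 512-cell and 0.660 between 128-cell and 512-cell. With 2 libraries per stage the deviations of replicate 2 mirror those of replicate 1. The values were not rescaled for this check. A shift of whole libraries in the same direction at each stage, shrunk by the pseudocount in low genes, could give such correlations too. The check alone therefore does not settle whether the numbers pair the libraries. With the libraries rescaled by median-of-ratios size factors, which take out such a shift, replicate number as a block still raised the calls. They went from 531 to 977 genes for 512-cell against 128-cell. For 512-cell against 256-cell they went from 241 to 559, and for 256-cell against 128-cell from 81 to 237. These counts argue against such a shift as the whole source. The labels do not say what a number shares. The fit without a block is kept, and values with replicate number as a block are given beside it. The unlabelled libraries have no replicate number in the labels. They were all given number 1 in the blocked fit, so their pairing cannot be checked; a number common to all 3 cancels in a difference between stages.

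Single genes were named by a fixed rule. It takes the 12 largest rises and 8 largest falls among passing genes with a symbol that is not clone-type, with no overlap between the compared libraries and a mean of at least 1 FPKM in the higher group. It adds up to 4 members of each list with the smallest adjusted p. Lists of gene symbols covered early zygotic genes, maternal mRNAs, the mitochondrial genome, small non-coding RNA genes, ribosomal proteins, histones, factors of the homeobox, Sox, Fox, Klf, Tbx, Gata and Her/Hes families, germ layer and axis patterning, the enveloping layer, the yolk syncytial layer, germ plasm, differentiated tissue, the cell cycle, and stress and immediate early genes. Lists for miR-430 and other microRNA genes matched 0 symbols and were not analysed here. Members of all lists were found by symbol, so whether such genes stand among the 1941 IDs without a symbol is not known. Values were given for 24 of 46 early zygotic genes and 14 of 32 germ layer genes. They were given for 5 of 16 enveloping layer genes and 55 of 234 factors of the homeobox to Her/Hes families. The minimum level admits a gene low in 1 group only through other libraries, so shares of a list lean towards genes that differ. The early zygotic list was written from general knowledge, and whether some members were first picked out from these libraries is not known. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. No list passed with an estimated correlation in any of the comparisons. For 512-cell against 128-cell the estimate was 0.853 for ribosomal proteins, 0.837 for the cell cycle and 0.701 for maternal mRNAs. It rests on few residuals of values that were not rescaled, so a shift of whole libraries can enter it. A test at such a correlation has little power. Tests, lists, the naming rule and most alternatives were fixed before the data were examined.

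Alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, median-of-ratios size factors over nuclear genes, 1 total over nuclear genes for all libraries, the replicate block, technical replicates kept separate, and leaving out each library in turn. The replicate block with size factors, fits without the mean-variance trend, and identical IDs counted once were chosen after seeing the data.

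The fits were tested on simulated data with 50 genes raised at each of 4 sizes among 7311 genes (7466 with unlabelled libraries). For 512-cell against 128-cell, log2 changes of 1, 2, 3 and 4 were recovered in 0%, 0%, 26% and 54% of genes with 0 other genes called. With the replicate block 30%, 94%, 100% and 100% were recovered, with 14 other genes called. For 256-cell against 128-cell the shares were 0%, 0%, 34% and 56%, and for 512-cell against 256-cell 0%, 0%, 8% and 44%. With the block, 13 and 17 other genes were called in these comparisons. For labelled against unlabelled RNA over the 3 stages 70%, 100%, 100% and 100% were recovered, but 67 other genes were called. At the 512-cell stage alone the shares were 0%, 0%, 18% and 38%. For the difference of the 512-cell against 128-cell change, 0% were recovered at every size without a block. With the block 50%, 82%, 100% and 100% were recovered, with 78 other genes called. A replicate effect of each gene, shared by the 3 stages, was built into the simulated labelled libraries. The block removes this effect, so its higher recovery was built in and decides nothing about pairing in the real libraries. The simulated values kept the real differences between library medians for all but low genes. A simulated change of 1 was therefore fitted at a median of 1.34 over the 3 stages, 1.82 at 512-cell and 1.96 in the difference of changes. In these fits with unlabelled libraries the other genes called do not measure false calls alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.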

Results

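Newly made RNA of zebrafish embryos was followed across 3 cleavage stages, with 2 labelled libraries and 1 unlabelled library at each of the 128-cell, 256-cell and 512-cell stages. Labelled libraries hold RNA that took up 4-thio-UTP after the 1-cell stage, plus background; unlabelled libraries show what the purification carries over without the label. The libraries had between 4035 genes (unlabelled 512-cell) and 7416 genes (labelled 512-cell replicate 1) at 1 FPKM or more. Median FPKM was 2.59 and 1.62 in the labelled 128-cell replicates, 3.21 and 1.49 at 256-cell and 3.10 and 1.42 at 512-cell. In the unlabelled libraries it was 2.52, 1.35 and 0.836 in stage order. Replicate 1 lay above replicate 2 by a median of 1.40-fold in FPKM + 1 at 128-cell, and 1.72-fold at both later stages. The pseudocount shrinks these folds in low genes. Size factors were 1.44 and 0.874 in the labelled 128-cell replicates, 1.66 and 0.779 at 256-cell and 1.44 and 0.686 at 512-cell. Across genes, which are not independent replicates, Spearman's correlation between replicates was 0.877, 0.849 and 0.870. The 10 most abundant genes took 72.2% and 74.4% of the FPKM sum in the labelled 128-cell libraries, and 44.3% and 39.9% in the labelled 512-cell libraries. In the unlabelled libraries these shares were 86.6%, 80.7% and 76.2%.

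Of 22 tested early zygotic genes, from 46 listed, 17 rose in labelled RNA from the 128-cell to the 512-cell stage. Most of the genes that rose have no symbol or stand in no list. The comparison asks which genes had more newly made RNA at the later stage. By limma, 369 of 7438 genes were higher at the 512-cell stage and 0 were lower (n = 2 technical replicates per stage). At an unadjusted p under 0.05, 599 genes were higher and 16 lower. The 369 genes had a median fitted log2 change of 3.04, at most 8.89, with a median SE of 0.56, against a median of -0.11 over all genes. Their median FPKM was 0.112 and 0.0963 in the labelled 128-cell replicates, 2.98 and 1.11 at 256-cell, and 12.9 and 6.05 at 512-cell. In the unlabelled libraries it was 0.0423, 0.0258 and 0.110. With the replicate number as a block, 726 genes were higher and 99 lower, the 369 among them. With size factors 525 were higher and 6 lower. The count fell to 210 without labelled 512-cell replicate 1 and to 245 without labelled 128-cell replicate 2. With 1 nuclear total for all libraries the all-gene median moved to -0.82 and 1 gene passed, where the 369 genes had a fitted median of 2.52 with a median SE of 0.89. The factors of that total were 0.566 and 0.772 in the labelled 128-cell replicates and 0.988 and 2.03 at 512-cell. They are larger in replicate 2, where the size factors are smaller, so this rescaling widens the gap between replicates.

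Among genes with an ordinary symbol the largest rise was that of grhl3; larger ones, up to the 8.89, lie among IDs without a symbol. grhl3 (ENSDARG00000078552), a grainyhead-like factor of surface epithelia, rose by a log2 of 6.27 ± 0.87 (SE, n = 2 per stage; adjusted p = 0.00376), from 0.744 and 1.18 FPKM to 237 and 81.7 FPKM. The zinc-finger genes znf1089 (ENSDARG00000088847), blf (ENSDARG00000043126) and znf1127 (ENSDARG00000093220) rose by 6.26 ± 0.83, 6.10 ± 0.83 and 5.39 ± 0.65. Of the hairy-related repressors, her11 (ENSDARG00000002707) rose by 5.73 ± 1.02 and her5 (ENSDARG00000008796) by 4.93 ± 0.69. The Iroquois homeobox gene irx7 (ENSDARG00000002601) rose by 5.51 ± 0.93 and the Kruppel-like factor klf17 (ENSDARG00000038792) by 5.51 ± 1.07. mxtx2 (ENSDARG00000015906), a homeobox factor of the yolk syncytial layer, rose by 5.36 ± 1.28 (adjusted p = 0.0379), from 10.0 and 2.08 FPKM to 574 and 84.9 FPKM. The forkhead gene foxd5 (ENSDARG00000042485) rose by 5.32 ± 0.72. The apelin receptor gene aplnrb (ENSDARG00000036670) rose by 5.35 ± 1.07, marcksl1b (ENSDARG00000035715) by 5.40 ± 0.87, and drll.3 (ENSDARG00000095635) by 5.53 ± 0.81. Without labelled 128-cell replicate 2, adjusted p was 0.054 for irx7, 0.104 for klf17, 0.184 for mxtx2 and 0.0575 for aplnrb. Without labelled 512-cell replicate 1 it was 0.162 for mxtx2.

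**Figure D1:**
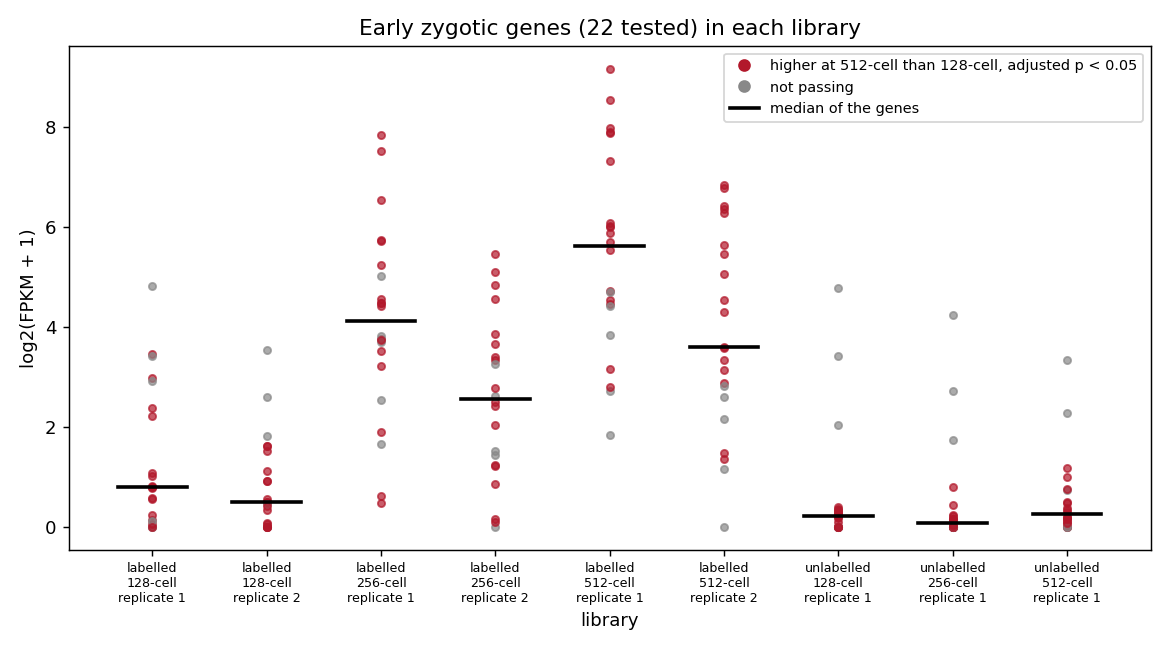
Level of the 22 tested early zygotic genes, as log2(FPKM + 1), in each of the 9 libraries, with a point per gene and a line at the median. The medians are 0.80 and 0.50 in the labelled 128-cell replicates, 5.63 and 3.59 at 512-cell, and at most 0.26 in the unlabelled libraries.

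Early zygotic genes rose together: 17 of 22 tested passed over all genes and 18 adjusted over the list alone, with a median of 4.52 above all genes. A gene near 0 at 128-cell was tested only through its later values, so this share leans towards genes that rose. Camera gave an adjusted p = 5.25e-29 at the preset correlation, and adjusted p = 0.406 with an estimated correlation. Among them, nnr (ENSDARG00000058917) was listed at 0 in both 128-cell libraries and at 25.5 and 11.2 FPKM at 512-cell. Without labelled 128-cell replicate 2 or labelled 512-cell replicate 1, 12 members passed. Of 46 factors of the homeobox, Sox, Fox, Klf, Tbx, Gata and Her/Hes families, 18 rose over all genes and 22 adjusted over the list alone. GATA3 rose by 4.90 ± 0.74 and FOXB1 by 3.75 ± 0.52. Their median was 1.40, with a camera adjusted p = 2.12e-14, and adjusted p = 0.604 with an estimated correlation. In the germ layer and axis patterning list, 7 of 11 rose, 9 adjusted over the list alone. The Nodal ligand ndr1 rose by 3.29 ± 0.73, its inhibitor lft2 by 4.28 ± 0.97 and the endoderm factor foxa3 by 2.33 ± 0.51. That list's camera adjusted p = 1.33e-11, and adjusted p = 0.418 with an estimated correlation; 4 members passed without labelled 128-cell replicate 2 and 1 without labelled 512-cell replicate 1. For ndr1 the adjusted p became 0.112 and 0.0883 without these libraries, and for lft2 it was 0.0539 without labelled 512-cell replicate 1. In the enveloping layer list, 3 of 4 rose (grhl3, klf17 and GATA3), also adjusted over the list alone, while TP63 was at -0.25 ± 0.50. Its camera adjusted p = 8.58e-07, and adjusted p = 0.406 with an estimated correlation. mxtx2 was the 1 tested gene of the yolk syncytial layer list.

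Stress and immediate early genes included 3 risers of 9, 4 adjusted over the list alone. The small heat shock gene HSPB1 rose by 4.46 ± 0.58 and FOS by 3.64 ± 0.80, while JUN was listed at 0 in both 128-cell libraries and at 2.40 and 1.06 FPKM at 512-cell (adjusted p = 0.0365). The list's camera adjusted p = 0.000689, and adjusted p = 0.604 with an estimated correlation; 1 member passed without labelled 128-cell replicate 2 and 1 without labelled 512-cell replicate 1. For FOS the adjusted p became 0.067 and 0.104 without these libraries, and for JUN 0.186 without labelled 128-cell replicate 1 and 0.123 without replicate 2. Of 10 histone genes 1 rose, h2ax, from 0 in both 128-cell libraries to 8.67 and 2.34 FPKM (adjusted p = 0.0143). h3f3a, which encodes a histone H3.3, went from 49.6 and 20.2 FPKM to 355 and 114 FPKM (adjusted p = 0.458, and 7.57e-05 with the block). Histones had a median of 0.96, with 1 gene adjusted over the list alone and 5 with the block. Their camera adjusted p = 0.00753, and adjusted p = 0.669 with an estimated correlation. actc1a, an alpha-actin of muscle and the 1 tested gene of differentiated tissue, was listed at 0 in both 128-cell libraries and at 3.35 and 1.09 FPKM at 512-cell (adjusted p = 0.0318, and 0.104 without labelled 128-cell replicate 1 or 0.0641 without replicate 2).

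Maternal mRNAs, the germ plasm and the cell cycle stayed outside the calls. By limma 0 of 28 maternal mRNAs passed, also adjusted over the list alone, with a median of -0.21; with the block 3 were higher and 2 lower. The Nodal co-receptor gene tdgf1 had 1.85 ± 0.79 (adjusted p = 0.582, and 0.00065 with the block), and the oocyte histone-mRNA binding gene slbp2 -0.82 ± 0.71 (adjusted p = 1, and 0.0213 with the block). The list's camera adjusted p was 0.167, and adjusted p = 0.790 with an estimated correlation. Of 9 germ plasm genes 0 passed, with a median of -0.02 and DAZL at -0.50 ± 0.75. Of 21 cell cycle genes 0 passed, with a median of 0.02. WEE1, a kinase that restrains entry into mitosis, had 2.28 ± 0.60 (adjusted p = 0.0731, and 0.000671 with the block). Of 60 genes in the ribosomal protein list 0 passed, also adjusted over the list alone, and 11 with the block. Their median was 0.44 and RPL39 had 2.52 ± 0.69 (adjusted p = 0.0846, and 0.00413 with the block). That list also holds kinases named RPS6KA and the binding protein gene rps19bp1, at 1.49 ± 0.50 (adjusted p = 0.257, and 0.00284 with the block). The ribosomal list's camera adjusted p = 0.0372, and adjusted p = 0.790 with an estimated correlation. Of 16 genes in the small non-coding RNA list 0 passed, with a median of -0.07; its members are mostly protein genes, and of the RNA genes Metazoa_SRP had -0.92 ± 1.07. Of 13 mitochondrial-genome genes 0 passed, with a median of -0.46 and a camera adjusted p = 0.00195 for lower, and adjusted p = 0.604 with an estimated correlation.

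**Figure D2:**
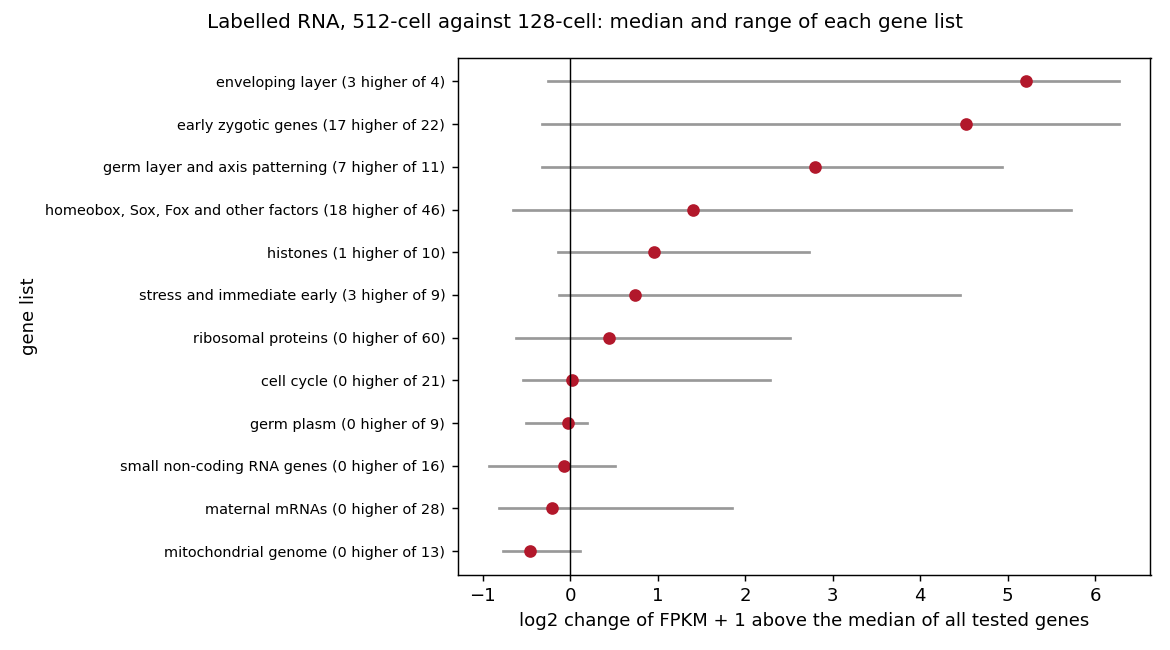
Median (point) and range (line) of the log2 change from 128-cell to 512-cell in labelled RNA, above the median of all tested genes, for each list with at least 3 tested genes. The enveloping layer list has the highest median, 5.21, and the mitochondrial genome the lowest, -0.46.

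From the 128-cell to the 256-cell stage, 14 of 22 early zygotic genes were higher in labelled RNA adjusted over the list alone. The list as a whole had a camera adjusted p = 1.68e-32 at the preset correlation, and adjusted p = 0.354 with an estimated correlation. The comparison asks which genes had gained new RNA by the earlier of the later stages. Over all genes 0 of 7438 passed by limma (n = 2 technical replicates per stage), with 256 at an unadjusted p under 0.05, of which 246 were higher. With the replicate block 234 were higher and 8 lower, and with size factors 81 were higher. With the block 15 early zygotic genes passed over all genes, and the list's median was 2.50. The zinc-finger gene blf had 4.30 ± 0.83 (adjusted p = 0.148, and 1.34e-05 with the block), from 1.12 and 0.467 FPKM to 52.4 and 22.5 FPKM. foxd5 had 3.51 ± 0.72 (adjusted p = 0.148, and 0.000118 with the block), irx7 3.85 ± 0.93 (0.219 and 1.92e-05), and her5 3.29 ± 0.69 (0.148 and 4.27e-05). Of 46 factors of the homeobox to Her/Hes families 9 were higher adjusted over the list alone and 14 with the block, among them GATA3 at 3.71 ± 0.74. In the enveloping layer list 3 of 4 were higher adjusted over the list alone (klf17 at 4.17 ± 1.07 and grhl3 at 3.46 ± 0.87), and mxtx2 had 3.77 ± 1.28. In the germ layer list 1 of 11 was higher adjusted over the list alone and 5 with the block, with lft2 at 2.70 ± 0.97 and ndr1 at 2.21 ± 0.73. FOS had 2.53 ± 0.80 (adjusted p = 0.474, and 0.0031 with the block). Maternal mRNAs had a median of 0.01 with camera's direction lower (adjusted p = 0.570), and the 13 mitochondrial genes a median of -0.52 with 0 passing (camera adjusted p = 5.28e-05, and adjusted p = 0.575 with an estimated correlation). The all-gene median was 0.03, and -0.60 with 1 nuclear total. Over all genes, leaving out 1 labelled library gave 2 (128-cell replicate 1), 23 (128-cell replicate 2), 7 (256-cell replicate 1), 75 (256-cell replicate 2), 70 (512-cell replicate 1) or 85 genes (512-cell replicate 2).

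From the 256-cell to the 512-cell stage, 3 early zygotic genes were higher in labelled RNA adjusted over the list alone. Over all genes 0 of 7438 passed by limma (n = 2 technical replicates per stage), with 335 at an unadjusted p under 0.05, of which 326 were higher. With the replicate block 361 were higher and 21 lower, and with size factors 240 were higher and 1 lower. With the block 15 early zygotic genes passed, and their median was 1.61. nnr had 2.88 ± 0.58 (adjusted p = 0.263, and 0.00271 with the block), from 2.73 and 0.821 FPKM to 25.5 and 11.2 FPKM. grhl3 had 2.78 ± 0.87 (0.479 and 0.00616), foxa3 2.04 ± 0.51 (0.328 and 0.0175), and polr3gla, which encodes a subunit of RNA polymerase III, 1.88 ± 0.44 (0.313 and 0.00946). The early zygotic list's camera adjusted p = 6.03e-18, and adjusted p = 0.719 with an estimated correlation. Among factors of the homeobox to Her/Hes families, 3 of 46 were higher adjusted over the list alone and 18 with the block, with SOX11 at 2.36 ± 0.51, klf2a at 2.23 ± 0.62 and ZIC2 at 2.21 ± 0.53. HSPB1, at 3.27 ± 0.58, was the 1 of 9 stress and immediate early genes higher adjusted over the list alone. In the germ layer list 1 of 11 was higher adjusted over the list alone, and the organizer gene GSC had 1.54 ± 0.69 (adjusted p = 1, and 0.0391 with the block). The maternal gene tdgf1 had 1.60 ± 0.79 (adjusted p = 1, and 0.00623 with the block). With the block 3 histone genes were higher, h3f3a among them (adjusted p = 0.00573 with the block). The all-gene median was -0.10, and -0.20 with 1 nuclear total. Over all genes the count became 2 without 128-cell replicate 1, 1 without 128-cell replicate 2, 84 without 256-cell replicate 1, 2 without 256-cell replicate 2 and 135 without 512-cell replicate 2.

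Labelled RNA held far more RNA of the mitochondrial genome than unlabelled RNA over the 3 stages, and more of the early zygotic regulators. The comparison asks which RNAs the purification enriched because of the label. All 13 mitochondrial genes were higher (n = 3 labelled and 3 unlabelled stage values), also adjusted over the list alone, by 5.51 to 6.42 with a median of 6.01. mt-nd4l and MT-ND4, subunits of complex I, were higher by 6.42 ± 0.72 and 6.38 ± 0.81, and MT-CO2 of complex IV by 6.24 ± 0.82. The 13 genes took between 12.8% and 42.7% of the FPKM sum in labelled libraries and between 0.367% and 0.456% in unlabelled ones. In labelled 128-cell replicate 1, mt-nd4l and mt-atp8 alone held 416770 and 274310 of the 885237 FPKM of the 13 genes. FPKM is scaled by transcript length, so these are not shares of reads. Camera gave an adjusted p = 4.22e-52, and adjusted p = 0.411 with an estimated correlation. Of 22 early zygotic genes 16 were higher, 18 adjusted over the list alone, with a median of 2.21. mxtx2 was higher by 4.95 ± 0.46, irx7 by 4.41 ± 0.44, klf17 by 4.39 ± 0.48 and aplnrb by 3.65 ± 0.41. That list's camera adjusted p = 1.56e-13, and adjusted p = 0.702 with an estimated correlation. With size factors 2 early zygotic genes passed, with a fitted median of 2.41, and 7 passed without labelled 128-cell replicate 2.

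**Figure D3:**
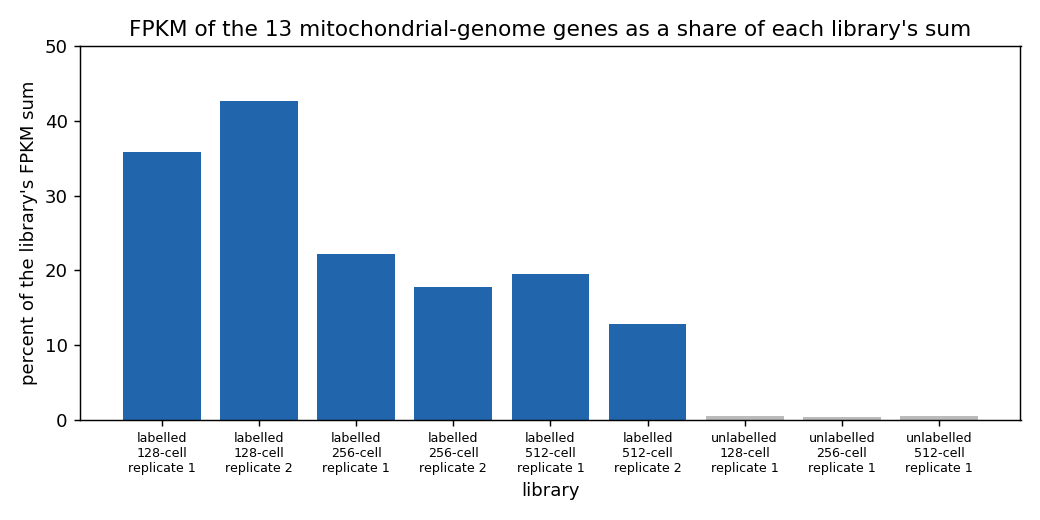
Share of each library's FPKM sum taken by the 13 mitochondrial-genome genes, in percent, with a bar per library. The 6 labelled libraries lie between 12.8% and 42.7% and the 3 unlabelled ones between 0.367% and 0.456%. FPKM is scaled by transcript length, so the bars are not shares of reads.

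Members of other groups also separated labelled from unlabelled RNA. Of 49 factors of the homeobox to Her/Hes families 18 were higher over all genes, and 23 higher and 1 lower adjusted over the list alone; 3 were higher and 1 lower with size factors. In the germ layer list 8 of 11 were higher, 9 adjusted over the list alone and 0 with size factors. Its fitted median was 2.04 as deposited and 1.97 with size factors, with lft2 at 2.51 ± 0.35 and the Wnt inhibitor dkk1b at 2.02 ± 0.34 as deposited. In the enveloping layer list grhl3, klf17 and GATA3 were higher, 3 of 4 (1 with size factors). That list's fitted median was 3.25 as deposited and 2.96 with size factors. The differentiated tissue gene actc1a did not pass (0.31 ± 0.34). Of 60 genes in the ribosomal protein list 15 were higher (10 with size factors), 26 adjusted over the list alone. RPS21 was higher by 1.46 ± 0.40; 0 of the list passed without unlabelled 256-cell or without unlabelled 512-cell. Of 10 histones 2 were higher (1 with size factors), h3f3a by 3.16 ± 0.58 and H2AZ2 by 2.27 ± 0.49. The germ plasm helicase gene DDX4 was higher by 2.01 ± 0.52, 1 of 9 germ plasm genes, 3 adjusted over the list alone and 2 with size factors. Of 28 maternal mRNAs tdgf1 alone passed, at 1.65 ± 0.42; with size factors 4 were higher and 2 lower. Of 21 cell cycle genes WEE1 and GMNN were higher (3 genes with size factors), by 0.87 ± 0.34 and 1.96 ± 0.66. Of 9 stress and immediate early genes 4 were higher (1 with size factors), FOS by 1.76 ± 0.35 and HSPB1 by 1.44 ± 0.34. In the small non-coding RNA list 4 of 16 were higher (2 with size factors), all protein genes, such as the splicing factor gene U2AF1 by 0.88 ± 0.37 and the RNase H gene RNASEH1 by 0.74 ± 0.34. Metazoa_SRP, a signal recognition particle RNA, had -3.57 ± 0.60 (adjusted p = 2.23e-06, and 0.0604 with size factors). Among other named falls, LYST had -1.73 ± 0.38 and the transcription factor genes bach2a and ZBTB20 had -1.65 ± 0.43 and -1.47 ± 0.39.

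Over the 3 stages limma called 913 of 7697 genes higher and 75 lower in labelled RNA, with a median fitted log2 difference of 0.33 over all genes. With size factors that median was 0.13, with 522 genes higher and 200 lower. With 1 nuclear total it was 0.28, with 1344 higher and 148 lower. With technical replicates kept separate 185 were higher and 29 lower, and at a minimum of 5 FPKM 531 and 69. The variance estimate of this fit rests wholly on the trend over all genes, so the SE of a gene leaves out its own spread. In simulated data 67 other genes were called, which could carry the kept differences between library medians. Calls of single genes are therefore uncertain, not only near the threshold. The 988 calls became 150 without unlabelled 256-cell, 203 without unlabelled 512-cell, 2880 without unlabelled 128-cell, 399 without labelled 128-cell replicate 1, 493 without labelled 256-cell replicate 1 and 652 without labelled 512-cell replicate 2.

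Stage by stage, mitochondrial RNA set labelled RNA apart at all 3 stages, while more early zygotic genes passed at the later ones. At 128-cell 6 of 7697 genes were higher and 0 lower in labelled RNA (n = 2 labelled and 1 unlabelled library), with 72 higher and 134 lower at an unadjusted p under 0.05. mt-nd4l was higher by 6.65 ± 0.88, and 13 of 13 mitochondrial genes passed adjusted over the list alone (1 over all genes). The other 5 have no symbol; among them, chosen after their values were seen, are ENSDARG00000080151 (adjusted p = 0.00168) and ENSDARG00000081280 (adjusted p = 0.00523), both listed at 0 in the unlabelled 128-cell library. Of the 22 early zygotic genes 0 passed, also adjusted over the list alone, with a median of 0.52 and mxtx2 at 2.48 ± 1.48. At 256-cell 87 genes were higher and 0 lower, with 301 and 25 at an unadjusted p under 0.05. They included 9 mitochondrial genes and 4 early zygotic genes, and 12 early zygotic genes passed adjusted over the list alone. irx7 was higher by 5.24 ± 0.96, znf1089 by 4.98 ± 0.81, blf by 4.29 ± 0.86 and GADD45B, a stress-inducible gene, by 4.59 ± 0.98. At 512-cell 286 genes were higher and 17 lower. Among them were all 13 mitochondrial genes and 14 early zygotic genes (18 adjusted over the list alone). mxtx2 was higher by 6.57 ± 1.48, irx7 by 6.24 ± 0.96, klf17 by 5.80 ± 1.18 and grhl3 by 5.40 ± 0.94. Of 49 factors of the homeobox to Her/Hes families 15 were higher at 512-cell, and h3f3a was higher by 5.11 ± 1.25. The stage counts of labelled against unlabelled RNA do not test whether stages differ. Each rests on 1 unlabelled library, which is assumed to vary like the labelled technical replicates.

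The all-gene median of labelled against unlabelled RNA was -0.18 at 128-cell, 0.43 at 256-cell and 0.73 at 512-cell on the deposited scale. With size factors it was 0.04, 0.11 and 0.21, and the 512-cell calls were 739 higher and 144 lower, against 130 and 24 with 1 nuclear total. With size factors 0, 1 and 5 of the 13 mitochondrial genes passed at the 3 stages, with fitted medians of 6.30, 5.89 and 5.68 against 5.93, 6.37 and 6.60 as deposited. Leaving out labelled replicates 1 and 2 in turn gave 19 and 27 genes (128-cell replicates), 18 and 28 (256-cell) and 11 and 12 (512-cell) in the 128-cell comparison. In the 256-cell comparison it gave 141 and 139, 113 and 251, and 160 and 170 in the same order. In the 512-cell comparison it gave 462 and 488, 613 and 665, and 246 and 582.

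Set against the unlabelled background, the change from 128-cell to 512-cell was higher for 14 of 22 early zygotic genes adjusted over the list alone. The list as a whole had a camera adjusted p = 6.74e-14 at the preset correlation, and adjusted p = 0.911 with an estimated correlation. The comparison asks whether the rise in purified RNA goes beyond what the purification carries over. Over all genes 0 of 7697 passed by limma (n = 2 labelled libraries and 1 unlabelled library per stage), with 563 higher and 5 lower at an unadjusted p under 0.05. The list's median was 3.37. blf had 4.65 ± 1.21, foxd5 4.15 ± 1.05 and her5 4.08 ± 0.96, each with an adjusted p = 0.197 over all genes. With the block the adjusted p was 0.000102 for blf, 0.000381 for foxd5 and 0.000108 for her5. nnr, listed at 0 in every unlabelled library, had an adjusted p = 0.197, and 0.000836 with the block. Of 49 factors of the homeobox to Her/Hes families 11 were higher adjusted over the list alone, and in the enveloping layer list 3 of 4. HSPB1 had 2.81 ± 0.89 (adjusted p = 0.218, and 0.00125 with the block). Of 28 maternal mRNAs 0 passed, with a median of 0.18, but 14 were higher with the block and 0 with size factors. Mitochondrial genes had 0 passing, also with the block, and a median of -0.16. The fitted all-gene median was 0.94, and 0.13 with size factors. With the block 2886 genes were higher and 36 lower, with size factors 144 and 2, and with both 561 and 84. The unlabelled libraries have no replicate number in the labels, so their pairing cannot be checked. The count was 148 without labelled 256-cell replicate 1, 202 without labelled 256-cell replicate 2, 226 without labelled 512-cell replicate 2 and 4 without labelled 128-cell replicate 1.

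The tables with 1 value per stage are taken to pool the same labelled libraries, so they are no independent data and allow no test. In the combined gene table, whose scaling between stages is not stated, median FPKM was 1.34, 2.37 and 3.12 in stage order, and the median 512-cell over 128-cell ratio was 2.04-fold. mxtx2 went from 2.98 to 496 FPKM, klf17 from 2.58 to 360 FPKM and grhl3 from 0.569 to 237 FPKM. Of its 9436 genes 453 lay at least 8-fold above that median ratio and 1 at least 8-fold below. In the transcript table, 627 of 11530 transcripts lay at least 8-fold above its median and 44 below. Across 7258 genes tested in both gene tables, which are not independent replicates, the log2 changes correlated at a Pearson's r of 0.953 and a Spearman's rho of 0.759.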

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

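The tests of scaling, carry-over and identical copies in these paragraphs were chosen only after the results were seen; the matching on level and the splits were chosen before theirs.

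The change from 128-cell to 512-cell differed between labelled and unlabelled RNA for 2922 genes with the replicate block, 146 with size factors and 645 with both, against 0 in the fit without either. The all-gene median of that difference was 0.94, and 0.13 with size factors. Adjusted over the list alone, 14 early zygotic genes differed.

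The 369 genes higher at 512-cell were weighed against 2 technical explanations. Size factors and 1 nuclear total both leave out the changing mitochondrial share: with size factors the median fitted log2 change was 3.04 (median SE 0.30) and 338 genes passed, and with 1 nuclear total it was 2.52, the median SE rose from 0.561 to 0.891 and 1 gene passed. If unlabelled RNA carried through the purification were the whole source, they would stand no higher than other genes against the unlabelled 512-cell library. Their median was 2.29 above all genes, with a lower quartile of 1.32. The genes were picked as high in the same labelled 512-cell libraries, which by itself raises this value, so it cannot settle carry-over. Their unlabelled 512-cell minus 128-cell change, a median of 1.01 above all genes, decides nothing, since they lie near the floor there (median FPKM 0.0423 and 0.110) while other genes fell. The rescaled values argue against scaling as the whole source. The early zygotic list was fixed before the data were examined. Its 22 tested genes had a median log2(FPKM + 1) of 5.63 and 3.59 in the labelled 512-cell libraries against 0.26 in the unlabelled one. At 256-cell the medians were 4.13 and 2.56 against 0.08, with 1 unlabelled library per stage. For this list the values argue against carry-over as the whole source. For the 369 genes as a whole, carry-over stays open.

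Among the 369 genes 52.8% of IDs lack a symbol, against 19.1% of other tested genes. With sets of identical IDs counted once the share was 50.6%, which argues against identical copies as the source. Sets of other genes matched on the labelled 128-cell FPKM had a median share of 38.2% and a range of 29.8% to 47.4% over 10000 sets. A low level at 128-cell may therefore account for part of the excess, and the question stays open. The smallest pool to draw from held 6 genes. Genes this low at 128-cell were tested only through higher values at later stages, so the matched genes may also rise. No biological explanation was tested.

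The mitochondrial genes were weighed against scaling. Over both rescalings the lowest fitted log2 difference among the 13 genes was 5.49. This value argues against scaling as the source. No biological explanation was tested.

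Of the 10 splits of the 6 stage values into groups of 3, 1 gave as many calls as the real one, which is the real split itself with 988 genes. The highest other split gave 770. With stage as a block it parts only 1 stage, so it repeats the labelled against unlabelled contrast of that stage. The other splits that part all 3 stages, and so mix the labels, called 0 genes. Still, 10 splits are too few for a share under 0.05.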

How the results depend on the processing

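Over all settings, values of named genes kept direction and side of the threshold in 4820 cases, lost their call in 246, gained it in 496, and changed direction in 102, all without a call in either setting. Counts of lists stayed within 1.5 times, or at 0 in both settings, in 1220 cases. They moved by more in 129, rose from 0 in 201 and fell to 0 in 49. Counts of calls moved more, and the cause was not tested except where fewer genes or libraries were used. Labelled 256-cell against 128-cell had 0 genes as reported, 82 with a pseudocount of 0.1, 81 with size factors, 46 without the trend, 242 with the replicate block, 237 with the block and size factors, and 2 to 85 with 1 library left out. 512-cell against 256-cell had 0, and 241 with size factors, 382 with the block, 559 with both and 0 to 135 with 1 library left out. 512-cell against 128-cell had 369, and 164 at a minimum of 5 FPKM, 1 with 1 nuclear total, 187 without the trend, 825 with the block, 977 with the block and size factors, and 210 to 519 with 1 library left out. Labelled against unlabelled over 3 stages had 988, and 600 at a minimum of 5 FPKM, 1492 with 1 nuclear total, 214 with technical replicates kept separate, and 150 to 2880 with 1 library left out. At 128-cell there were 6, and 3 without the filter, 10 at a minimum of 5 FPKM, 28 with 1 nuclear total, 23 without the trend and 11 to 28 with 1 library left out. At 256-cell there were 87, and 157 with a pseudocount of 0.1 and 113 to 251 with 1 library left out. At 512-cell there were 303, and 492 with a pseudocount of 0.1, 180 at a minimum of 5 FPKM, 883 with size factors, 154 with 1 nuclear total, 179 without the trend and 246 to 665 with 1 library left out. The 512-cell against 128-cell change of labelled minus unlabelled RNA had 0, and 6 with a pseudocount of 0.1, 146 with size factors, 2922 with the block, 645 with both and 0 to 226 with 1 library left out. A test on read counts, a test of isoforms and a fit of the tables with 1 value per stage were not run. Sequencing depth limits low values by an unknown amount.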

Other observations

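The test of symbol families and the ratio between stages were chosen only after the list of higher genes was seen; the test against the unlabelled 128-cell library and its matching on level were each chosen before their result.

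A larger share of zinc-finger, Sox and Kruppel-like genes was higher at 512-cell than of other symbols. The hypothesis was that some families of symbols with the same leading letters hold more of the higher genes. Of 5537 symbols 139 (2.51%) were higher, and 4 of 188 families passed Fisher's exact test. These were znfl with 6 of 7 (adjusted p = 2.90e-07), znf with 8 of 63 (adjusted p = 0.0146), sox with 3 of 6 (adjusted p = 0.0184) and klf with 3 of 8 (adjusted p = 0.0372). Genes of a family are not independent where their sequences share reads.

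Some of the genes higher at 512-cell may already be made at 128-cell. The hypothesis was that both labelled 128-cell libraries lie above the unlabelled one more often for these genes than for others. Only genes with a mean of at least 0.3 FPKM over the 128-cell libraries were used, which leaves out most of the 369. With size factors both lay above for 87 of 102 genes (85.3%) against 2748 of 6960 (39.5%), Fisher's exact p = 3.91e-21. As deposited they did for 86 of the 113 genes left (76.1%) against 1108 of 6978 (15.9%), Fisher's exact p = 1.80e-44. A minimum level favours low genes with higher labelled values; other genes matched on the mean 128-cell FPKM had a median share of 44.1%, from 27.5% to 60.8% over 10000 sets, though the smallest pool held 2 genes. This argues against the minimum as the whole source for the 102 genes. Genes are not independent replicates, and the unlabelled stage has 1 library. RNA or reads of the 512-cell libraries present in the 128-cell libraries could give such a signal at a constant ratio. Among 72 genes at 50 FPKM or more at 512-cell, the 90th percentile of the ratio was 14.7 times the 10th in replicate 1 and 3.94 times in replicate 2, so this explanation stays open. The ratios correlated between replicates at a Spearman's rho of 0.807 across these genes.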
